A study of Mus musculus with 6 samples.

How the data were processed

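Total RNA of the RPE from BALB/c mice, extracted with Trizol and a column kit and labelled with biotin by a small-sample protocol per the labels, was hybridised to 6 Affymetrix mouse arrays, 3 from dark-adapted and 3 from light-damaged mice. The deposited values are log2 expression values per probe set, and RMA, which corrects background, normalizes across arrays and summarises probes, is named in the submitters' processing notes. Its version and the arrays normalized together are not given in the sources used here. That the unit is log2 was read from the values, which lay between 3.72 and 14.82 with array medians of 7.43 to 7.48. RMA compresses small differences near the background and near saturation, so differences of very dim or very bright genes are understated. The values carry no detection calls, and no genome coordinates were used.

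The table held 45101 probe sets, 64 of them controls. The platform annotation, dated 2016, gave exactly 1 gene symbol to 34945, several to 932 and none that was used here to 9160. The Entrez number of 34741 of the 34945 was found in the GRCm38.p6 gene table, and 0 symbols changed. A gene with several probe sets was represented by the one with the highest mean over all 6 arrays, a choice blind to the groups, which left 18193 genes, 9010 of them with more than 1 probe set. Of these genes, 948 were measured by s_at and 749 by x_at probe sets, which can bind related transcripts. For the 152 genes followed by name there were 118 further probe sets, of which 23 had the opposite sign, and in 0 of these did both probe sets have an unadjusted p under 0.05 with the block. Of 88 named genes called with the block, 36 had another probe set, and for 15 of these at least 1 other probe set did not go the same way at an unadjusted p under 0.05. Vim, Mcm5, Rrm2, Socs3, Tgfbi, C1qb and Snai2 were measured by x_at and Ms4a6d, S100a8 and Car14 by s_at probe sets.

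Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust settings, two-sided), with Benjamini-Hochberg adjustment over all genes and calls at an adjusted p under 0.05, without covariates and with 4 residual degrees of freedom. Gene lists were tested with limma's camera at a preset correlation of 0.01 for lists of at least 5 measured genes, with Benjamini-Hochberg adjustment over lists, and also with an estimated correlation and with fry. The 33 lists held 542 genes, of which 493 were measured, 2 of them through older symbols, and some members are not named here. They covered the visual cycle, RPE identity, melanin synthesis, RPE transport and junctions, phagocytosis and lysosome, photoreceptors, Müller glia, inner retinal neurons, endothelium, pericytes and fibroblasts, macrophages and microglia, neutrophils, lymphocytes, red blood cells, sex chromosome genes, G1/S and G2/M, complement, cytokines and chemokines, the IL-6 family and acute phase, interferon response, antioxidants, heat shock, the unfolded protein response, immediate early genes, p53 and apoptosis, matrix remodelling, epithelial-mesenchymal transition, growth factors, cholesterol synthesis, the circadian clock, oxidative phosphorylation and ribosomal proteins. Single values per array were compared by exact two-sided permutation over 20 assignments, the smallest possible p being 0.10, for 16 measures. The smallest p adjusted over these 16 was 0.40.

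The labels number the replicates 1 to 3 in both groups without saying that a number marks a shared animal, litter or day. Deviations of same-numbered arrays from their group means correlated at 0.89, 0.62 and 0.86, across genes, all above the bound of 0.1 set before the data were examined, so the numbers were taken to pair the arrays. This rests mostly on replicate 1, since dark-adapted replicate 2 correlated at 0.65 with light-damaged replicate 3, and dark-adapted replicate 3 at 0.61 with light-damaged replicate 2. Deviations from a group mean cancel within the group, so a shared replicate 1 difference alone makes replicates 2 and 3 correlate across groups. The difference of replicate 3 minus replicate 2 correlated at 0.33 between groups, so the pairing of replicates 2 and 3 is less sure. With the numbers taken to pair the arrays, results with the replicate number as a block, with 2 residual degrees of freedom, are given where they change a call or a count.

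Named genes were chosen by a rule fixed before the data were examined: the 12 largest rises and falls among called genes whose groups do not overlap, without clone names, and up to 4 members of each list with the smallest unadjusted p, plus the visual cycle and sex chromosome lists in full. The same rule on the fit with the replicate block, with 3 of 3 pairs going the same way in place of separate groups, was added after seeing the data, and other list members were named after their values were seen. Alternatives covered normalization, a filter on dim genes, a pseudocount of 16, other probe set choices, limma settings, array weights, the replicate block, a photoreceptor covariate, an ordinary unmoderated test and leaving out each array.

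The scripts were tested on simulated data for this comparison with 18193 genes, drawn from the real means, replicate effects and the variance distribution that limma fitted, with 200 changed genes in each of 20 simulations. Without the block, 0% of genes changed by 0.5 on the log2 scale, 11.5% of those changed by 1, 74.9% of those changed by 2 and 91.7% of those changed by 3 were recovered. With the block, 9.6%, 92.2%, 99.7% and 100% were recovered, and 5.28% of calls were false. Same-numbered arrays shared their replicate effect in the simulations, so the rates with the block hold only if the numbers pair the arrays. When each gene kept its own moderated variance, 9.43% of calls with the block were false. A list of 20 genes raised by 0.5 was called in 20 of 20 simulations with and without the block, and 0 of 600 random lists were called, in simulations that hold no correlation between genes beyond the replicate effects. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.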

Results

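Gene expression was measured in the retinal pigment epithelium (RPE), the pigmented cell layer behind the photoreceptors that renews visual pigment and engulfs shed outer segments. The mice were BALB/c, an albino strain. All had 1 week of dark adaptation, and some of them were then placed under white fluorescent light of 6000 lux for 1.5 h, with RPE taken 24 h after the exposure. There were 6 Affymetrix arrays in 2 groups, 3 from dark-adapted and 3 from light-damaged mice, and the number of arrays limits the precision. Median log2 values lay between 7.43 and 7.48 per array. The labels do not say whether the 3 samples of a group came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical. The comparison asked which transcripts of the RPE change after damaging light. Differences below are light-damaged minus dark-adapted, on the log2 scale, ± standard error, with n = 3 per group.

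Among 18193 genes, 9 rose in light-damaged RPE and none fell at an adjusted p under 0.05 in limma. The largest rise was that of Mmp3, stromelysin-1, a secreted matrix protease, from 7.14 ± 0.31 (SD, n = 3) to 12.75 ± 0.40, a difference of 5.61 ± 0.25 or 48.8-fold (limma adjusted p = 0.0022). The acute phase protease inhibitor Serpina3n rose 22.2-fold and the elastase inhibitor Serpinb1a 18.8-fold, both with an adjusted p of 0.0019. Ccl12, a chemokine that draws monocytes, rose 9.37-fold (adjusted p = 0.0047), and Rbp4, the plasma carrier of retinol, 8.08-fold (adjusted p = 0.0090). The other 4 were the macrophage elastase Mmp12 at 7.39-fold, the myeloid lectin receptor Clec4a3 at 4.01-fold, the macrophage chitinase-like gene Chil3 at 3.35-fold, and the leukocyte actin-bundling gene Lcp1 at 3.13-fold. Their adjusted p-values were 0.0231, 0.0066, 0.0347 and 0.0347. Mmp12 lost its call with quantile normalization and Chil3 lost its call with median centring. At an unadjusted p under 0.05 there were 1080 genes, 720 higher and 360 lower. Chance alone would give a share of 0.05 of the 18193 genes, so this total is little above chance in this fit. The fit without a block counts differences between replicates as noise. With the replicate number as a block, described below, the total was 3465, 1724 higher and 1741 lower. Without both replicate 1 arrays, a setting chosen after seeing the data, it was 2918. Leaving out 1 array left Mmp3, Serpina3n and Serpinb1a called in all 6 cases, whereas the number of genes called was 4 without dark-adapted replicate 1, 3 without dark-adapted replicate 2, 4 without dark-adapted replicate 3, 12 without light-damaged replicate 1, 3 without light-damaged replicate 2 and 3 without light-damaged replicate 3.

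**Figure D1:**
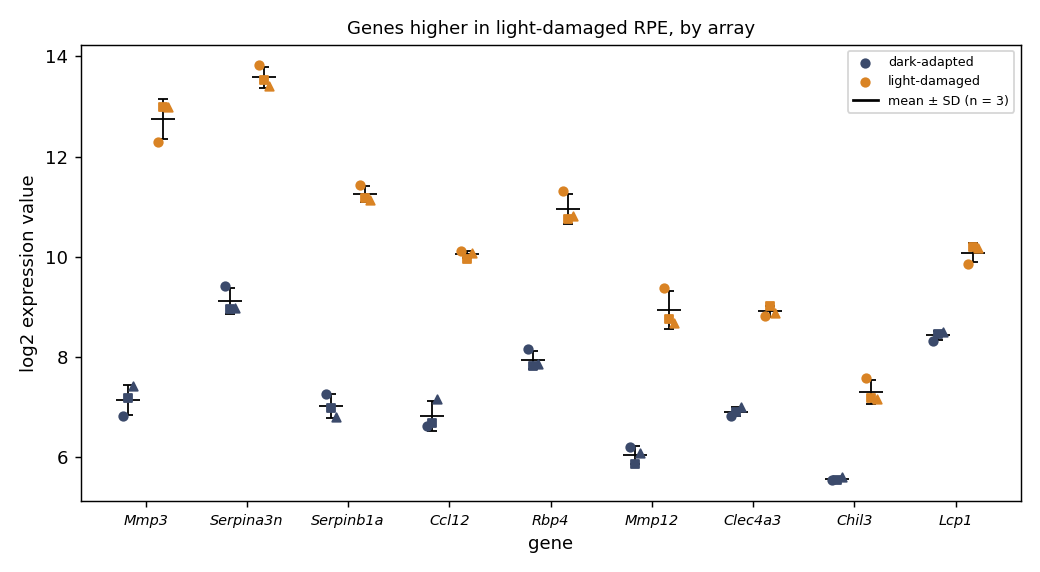
Log2 expression value (vertical axis) of the 9 genes called in the comparison without a block, for each array, with circles, squares and triangles for replicates 1, 2 and 3 and black marks for mean ± SD (n = 3). All light-damaged arrays lie above all dark-adapted arrays for each gene, with Mmp3 at 7.14 against 12.75 on average.

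The replicate 1 arrays of both groups stood apart from the other 4. The first principal component took 74.4% of the variance and placed them at -38.60 and -68.73, against 18.76 to 34.02 for the others, and the second took 15.3% and parted the groups. The difference between the Gapdh 3′ and 5′ control probe sets, a sign of RNA quality or labelling, was 2.45 and 2.48 in the replicate 1 arrays and 1.54 to 1.80 in the others. The mean of the 18S rRNA control probe sets was 11.38 and 10.72 in the replicate 1 arrays of dark-adapted and light-damaged mice and 12.98 to 13.30 in the others, and it was lower in the light-damaged array in 3 of 3 pairs (exact two-sided permutation p = 0.50). Arrays with the same replicate number deviated together, and with the replicate number as a block limma called 908 genes, 559 higher and 349 lower, including all 9 above. All 908 went the same way in 3 of 3 pairs, which calls of a paired fit nearly always do. The groups did not overlap for 614 of them. Over all genes 10.3% had groups that did not overlap. For arrays without shared replicate effects chance would give 10%. The replicate 1 arrays of both groups deviated together, which makes such separation rarer, so 10% overstates the chance share here. Without both replicate 1 arrays, an alternative chosen after seeing the data, 793 genes were called, of which 602 were among the 908. The fit with the block called 1245 genes without pair 1, 677 without pair 2 and 228 without pair 3, settings also chosen afterwards. Without a pair, fewer residual degrees of freedom remain than the 2 of the fit with all pairs. These counts thus lean heavily on the variance that limma shares across genes and are weak checks of the 908.

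**Figure D2:**
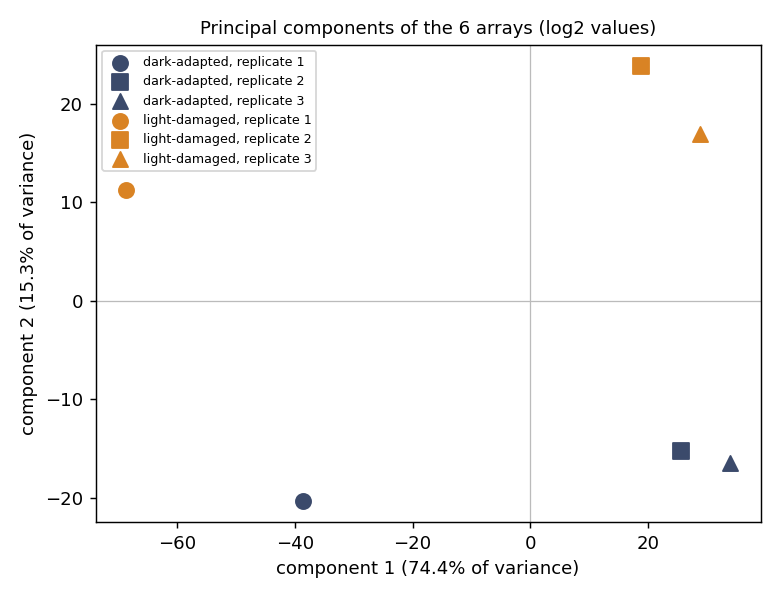
Scores of the 6 arrays on the first principal component (horizontal axis, 74.4% of the variance) and the second (vertical axis, 15.3%), computed on the log2 values of 18193 genes, with colour for group and marker shape for replicate. The replicate 1 arrays lie at -38.60 and -68.73 on the first component, and the groups lie on opposite sides of 0 on the second.

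With the replicate block, and by a rule chosen after seeing the data, the 12 largest rises added 6 genes to the first 6 above. Lcn2, an iron-siderophore binding protein, rose 14.6-fold (3.87 ± 0.23, limma adjusted p = 0.0010). Socs3, an inhibitor of cytokine signalling measured by an x_at probe set that can bind related transcripts, rose 7.39-fold. Its 2 dimmer probe sets gave 2.49 and 0.84 on the log2 scale against 2.88. The transcription factor Cebpd and the metalloprotease inhibitor Timp1 each rose 6.39-fold, Chil1, a secreted chitinase-like protein, 5.41-fold and the myeloid gene Ms4a6d 5.28-fold, the last by an s_at probe set of the same kind of limit. A second, dimmer probe set of Cebpd gave 0.84 on the log2 scale against 2.68. The largest falls were those of Glb1l3 at -2.02 ± 0.22, the secreted BMP and Wnt antagonist Sostdc1 at -1.97 ± 0.14 and the short-wavelength cone opsin Opn1sw at -1.72 ± 0.15, with adjusted p-values of 0.0066, 0.0020 and 0.0041. The second probe set of Opn1sw gave -0.59. Spc25, a kinetochore component, fell by 1.61, while its second probe set gave -0.13, and the second probe sets of Ddc and Myl4, both named next, gave 0.10 and 0.04. The potassium channel subunit Kcne2 fell by 1.42, the aromatic amino acid decarboxylase Ddc by 1.15 (-1.15 ± 0.09), and the growth factor Bmp6 by 1.14 (-1.14 ± 0.12). Dleu7, Myl4, Rabgef1, Ccn4 and Polg2, which completed the 12, had differences of -1.48, -1.25, -1.19, -1.16 and -1.14. None of these falls and none of the 6 added rises passed without the block.

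Gene lists fixed before the data were examined are described next, with rises and falls counted at an adjusted p under 0.05 over all genes with the replicate block unless stated, and errors from that fit. Camera, with a preset correlation of 0.01, called 22 of 32 lists without the block, 15 higher and 7 lower, and 21 of the 22 with it. With an estimated correlation it called none, the smallest adjusted p being 0.0644 without the block and 0.3906 with it.

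Of 16 genes of the IL-6 family and acute phase list, 14 rose and none fell, and the median difference was 1.62. Serpina3n (4.47 ± 0.09), Lcn2 (3.87 ± 0.23) and Socs3 (2.88 ± 0.19) led, and Stat3, the transcription factor through which IL-6 signals, rose 2.02-fold. The receptor subunits Osmr and Il6st rose 3.05-fold and 1.64-fold. Without the block 1 member passed over all genes, and 13 rose when adjusted over the list alone. The camera adjusted p was 6.7e-27, and the adjusted p = 0.0644 with an estimated correlation.

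Of 20 markers of macrophages and microglia, 16 rose and none fell, with a median of 0.93. The lysosomal glycoprotein gene Cd68 rose 4.31-fold, the Fc receptor gene Fcgr1 2.50-fold, Cd53 2.24-fold and the lysozyme gene Lyz2 2.19-fold. The second probe set of Fcgr1, of nearly the same level, gave a log2 difference of 0.34 against 1.32. That of Cd53, a dimmer one, gave 0.18 against 1.17. The complement components C1qa, C1qb and C1qc rose 1.51-fold, 1.91-fold and 1.91-fold. Without the block no member passed over all genes, and 12 rose when adjusted over the list alone. By camera the adjusted p was 2.5e-20, and the adjusted p = 0.1094 with an estimated correlation. Of 9 neutrophil markers, the calgranulin genes S100a8 and S100a9 rose 3.73-fold and 2.14-fold, and the other 7 did not pass. Adjusted over the list alone, 2 rose without the block and 3 with it, and camera gave an adjusted p of 1.3e-04, with an adjusted p = 0.3159 with an estimated correlation. With the mean of the photoreceptor list as a covariate, the neutrophil median was -0.07 against 0.21, and the call was lost (camera adjusted p = 0.9105). That mean was itself lower in the light-damaged array in 3 of 3 pairs, and on average lower in replicate 1. The lost call therefore does not show a cause. No lymphocyte marker passed among 8 over all genes, and 1 rose when adjusted over the list alone with the block. Camera gave an adjusted p of 0.3087 for lymphocytes.

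All 22 interferon response genes measured had a difference above 0, and 10 rose, with a median of 0.64. Ifit1 (1.22 ± 0.09) and the transcription factor Irf9 (1.13 ± 0.19) rose 2.33-fold and 2.18-fold, and the antigen-processing genes Tap1, Psmb8 and Psmb9 rose 2.21-fold, 1.90-fold and 1.87-fold. When adjusted over the list alone, 13 rose without the block and 18 with it. As a group the list had a camera adjusted p of 3.0e-21, and the adjusted p = 0.0644 with an estimated correlation. Of 22 cytokines and chemokines, 4 rose, namely Ccl12, Ccl3 (2.59-fold), Ccl8 (1.81-fold) and Ccl2 (1.74-fold), all attractants of leukocytes. Ccl12 was the 1 member called without the block, and 2 rose without the block when adjusted over the list alone. For the whole list the camera adjusted p was 2.9e-11, and the adjusted p = 0.1661 with an estimated correlation. With the photoreceptor covariate its median was 0.007 against 0.44, and the call was lost (camera adjusted p = 0.3187). Of 9 complement genes, Serping1, C1ra and Cfi rose 1.94-fold, 1.85-fold and 1.64-fold. With members adjusted over the list alone, 4 complement genes rose with the block and none without it. The camera adjusted p was 0.0027 for complement, and the adjusted p = 0.1661 with an estimated correlation.

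Matrix remodelling and wound response genes rose in 8 of 23 cases and fell in none. Mmp3 was the 1 member called without the block, and 5 rose without the block when adjusted over the list alone. Next to Mmp3 and Timp1, the hyaluronan receptor gene Cd44 rose 2.36-fold, Tgfbi 2.26-fold and the fibronectin gene Fn1 1.82-fold. By camera the adjusted p was 2.0e-09, and the adjusted p = 0.1094 with an estimated correlation. Of 14 genes of epithelial-mesenchymal transition, S100a4 (4.36-fold), the intermediate filament gene Vim (2.43-fold) and Fn1 rose. The same 3 is the count adjusted over the list alone in both fits. The transcription factors Snai1, Snai2, Twist1, Zeb1 and Zeb2 did not pass. As a group the list had a camera adjusted p of 0.0099, and the adjusted p = 0.1661 with an estimated correlation. Of 12 markers of pericytes and fibroblasts, Col3a1, Pdgfra and Tagln rose 1.76-fold, 1.66-fold and 1.49-fold, 1 rose without the block when adjusted over the list alone, and camera gave an adjusted p of 0.0092, with an adjusted p = 0.1661 with an estimated correlation. Of 14 endothelial markers, Vwf rose by 0.68 ± 0.11 on the log2 scale and the other 13 did not pass (camera adjusted p = 0.1113). Adjusted over the list alone, 1 endothelial marker rose with the block and none without it.

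Of 21 genes of the G1/S part of the cell cycle, 9 rose and none fell, with a median of 0.44. Mcm5, a subunit of the replicative helicase, rose 2.86-fold, Uhrf1, which maintains DNA methylation, 2.68-fold, and the ribonucleotide reductase gene Rrm2 2.55-fold. Mcm5 and Rrm2 were measured by x_at probe sets, and the other probe sets gave 0.13 and 0.22 for Rrm2 and 0.17 for Uhrf1 on the log2 scale, none with an unadjusted p under 0.05. When adjusted over the list alone, 8 rose without the block and 13 with it. For the whole list the camera adjusted p was 5.5e-13, and the adjusted p = 0.0644 with an estimated correlation. Of 25 G2/M genes, Mki67 (2.08-fold) and Birc5 (1.66-fold) rose and the rest did not pass, with a median of 0.09. With members adjusted over the list alone, 1 G2/M gene rose without the block and 2 with it. The camera adjusted p was 0.0041, and the adjusted p = 0.3233 with an estimated correlation. Of 17 genes of the p53 and apoptosis list, Gadd45g (2.01-fold), the pro-apoptotic Bid (1.90-fold), the cyclin-dependent kinase inhibitor Cdkn1a (1.85-fold) and Gadd45b (1.61-fold) rose. The other probe sets of Bid, both dimmer, gave 0.21 and 0.23 on the log2 scale against 0.93. Adjusted over the list alone, 2 genes of this list rose without the block and 5 with it. By camera the adjusted p was 0.0063, and the adjusted p = 0.1661 with an estimated correlation. Immediate early genes rose in 6 of 19 cases, with Atf3 at 3.12-fold, Junb at 1.83-fold and Myc at 1.69-fold. When adjusted over the list alone, 2 rose without the block and 11 with it. As a group the list had a camera adjusted p of 7.8e-08, and the adjusted p = 0.1661 with an estimated correlation.

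Stress lists were mixed. Of 20 antioxidant and NRF2 genes, the glutathione transferase gene Gsta3 rose 2.09-fold and the heme oxygenase gene Hmox1 2.00-fold, while Nqo1 fell by 0.87 and Me1 by 0.61 on the log2 scale (camera adjusted p = 0.1675). With members adjusted over the list alone, 1 rose and 1 fell without the block. Of 16 genes of the unfolded protein and integrated stress response, Atf3 and Ddit3 (1.46-fold) rose. The same list gave 1 rise without the block when adjusted over the list alone. Its camera adjusted p was 0.0382 without the block and 0.0717 with it, and the adjusted p = 0.3518 with an estimated correlation. No heat shock gene passed among 11, also when adjusted over the list alone, and the camera adjusted p was 0.0735 with a median of 0.18 in all arrays, and 0.0011 with a median of 0.27 without the replicate 1 arrays. Both used the preset correlation, and the heat shock adjusted p in all arrays was 0.5032 with an estimated correlation. Of 20 growth and survival factors, the vasoactive peptide gene Edn2 rose 4.62-fold and Fgf1 fell by 0.51. Camera gave this list a downward direction without the block (adjusted p = 0.5880), while its median was 0.03 and its mean 0.06. Adjusted over the list alone, 2 growth factors rose and 5 fell with the block and none passed without it.

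Most genes of the RPE lists had a difference below 0, but few passed. All 9 visual cycle genes measured, which regenerate the chromophore of visual pigment, had a difference below 0, with a median of -0.62. The median was -0.89, -0.32 and -0.54 in pairs 1, 2 and 3, and -0.40 without the replicate 1 arrays, with 1 visual cycle gene called there. Rrh fell by 0.82 (-0.82 ± 0.09), Rdh10 by 0.74 (-0.74 ± 0.15) and the retinol esterifying enzyme Lrat by 0.69 (-0.69 ± 0.11). The isomerase gene Rpe65 had a difference of -0.61 ± 0.15 (adjusted p = 0.0738), and Rdh11, Rlbp1, Stra6, Rgr and Rdh5 had differences of -0.95, -0.62, -0.53, -0.41 and -0.31 that did not pass. When adjusted over the list alone, 1 fell without the block and 9 with it. For the whole list the camera adjusted p was 1.8e-08, and the adjusted p = 0.1832 with an estimated correlation. Of 18 RPE identity genes, the lactate transporter gene Slc16a8 (-0.74 ± 0.13), the potassium channel gene Kcnj13 (-0.56 ± 0.09) and the melanosome gene Pmel (-0.52 ± 0.09) fell, and the transcription factor genes Otx2 and Mitf had -0.37 and -0.46 and did not pass. With members adjusted over the list alone, 7 fell with the block and none without it. The camera adjusted p was 8.5e-06, and the adjusted p = 0.1661 with an estimated correlation. Of 12 melanin synthesis genes, Gpr143, Oca2 and Pmel fell, by 0.82, 0.82 and 0.52, the same number as with the block when adjusted over the list alone. By camera the adjusted p was 1.0e-05, and the adjusted p = 0.1669 with an estimated correlation. The melanin synthesis median was -0.46, 0.04 and -0.43 in pairs 1, 2 and 3, and -0.16 without the replicate 1 arrays against -0.29 in all arrays. Of 21 genes of RPE transport and junctions, Slc4a5, Car14, Slc16a8 and Kcnj13 fell, the bicarbonate transporter gene Slc4a5 by 0.80 and the carbonic anhydrase gene Car14 by 0.75. Adjusted over the list alone, 4 fell without the block, and 7 fell and 1 rose with it. As a group the list had a camera adjusted p of 2.6e-04, and the adjusted p = 0.1661 with an estimated correlation. Without the replicate 1 arrays the transport and junctions list was not called (camera adjusted p = 0.0967, median -0.08 against -0.14 in all arrays), and its median was -0.49 in pair 1, 0.04 in pair 2 and -0.06 in pair 3. Of 16 phagocytosis and lysosome genes, Pros1, a ligand of the engulfment receptor Mertk, rose 1.72-fold. Camera gave the list an adjusted p of 0.3524, and 0.6880 with an estimated correlation. Without the replicate 1 arrays it was 0.0083 at the preset correlation, where the median was 0.18 against 0.03. When adjusted over the list alone, 1 of the 16 genes rose without the block and 2 with it.

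Photoreceptor transcripts, present in these RPE samples, were lower as well. All 22 measured had a difference below 0, 10 fell, and the median was -0.54. The cone genes Opn1sw (-1.72 ± 0.15), Arr3 (-0.92 ± 0.10) and Gnat2 (-0.89 ± 0.11) fell furthest among those that passed, followed by the rod outer segment gene Rom1 (-0.71 ± 0.13). A second, dimmer probe set of Opn1sw gave -0.59. The arrestin gene Sag had a mean of 14.46 in dark-adapted arrays and a difference of -0.10, which did not pass. With members adjusted over the list alone, 4 fell without the block and 19 with it. For the whole list the camera adjusted p was 5.0e-14, and the adjusted p = 0.2098 with an estimated correlation. The mean of the list was lower in light-damaged arrays in 3 of 3 pairs, from 12.42 ± 0.37 to 11.84 ± 0.44 (SD, n = 3; exact two-sided permutation p = 0.20, with 0.10 the smallest that 3 against 3 allows). This mean averaged 11.68 in the replicate 1 arrays and 12.35 in the others. As a covariate it thus followed both the group and the replicate 1 difference, and shifts with it do not show a cause. With the photoreceptor covariate, the visual cycle median was -0.12 (camera adjusted p = 0.2643) against -0.62 without it. RPE identity and RPE transport and junctions lost their calls with the covariate although the former median grew and the latter hardly moved, at -0.39 against -0.32 (adjusted p = 0.0620) and -0.14 in both fits (adjusted p = 0.2909). Melanin synthesis stayed called, at -0.37 against -0.29 (adjusted p = 8.5e-04). Of 15 markers of inner retinal neurons none passed over all genes and 2 fell when adjusted over the list alone with the block. The camera adjusted p was 0.0020, and the adjusted p = 0.1661 with an estimated correlation. Of 10 Müller glia markers, the filament gene Gfap rose 1.67-fold, with log2 differences of 1.15 and 1.84 in its s_at probe sets against 0.74, and the rest did not pass. The Müller glia list had a camera adjusted p of 0.8553, and 0.9291 with an estimated correlation. Without the replicate 1 arrays it was 0.0371 at the preset correlation. Adjusted over the list alone, 2 rose and 1 fell with the block.

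Among the other lists, the clock output gene Hlf fell by 0.64, 1 of 15 circadian genes, with a camera adjusted p of 0.0101 and an adjusted p = 0.2050 with an estimated correlation. The ribosomal protein gene Rps6 rose 1.46-fold, and all 11 ribosomal protein genes measured had a difference above 0, with a camera adjusted p of 1.0e-05 and an adjusted p = 0.2098 with an estimated correlation. When adjusted over the list alone, 3 ribosomal protein genes rose and 1 circadian gene fell with the block, and none did without it. Of 5 red blood cell markers, Ermap fell by 1.02, also when adjusted over the list alone without the block, with a camera adjusted p of 0.1293. No gene of cholesterol synthesis passed among 13 and none of oxidative phosphorylation among 20, also when adjusted over the list alone, with camera adjusted p-values of 0.0914 and 0.1014. In all, 3 list genes were called without the block and 114 with it, 89 higher and 25 lower.

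**Figure D3:**
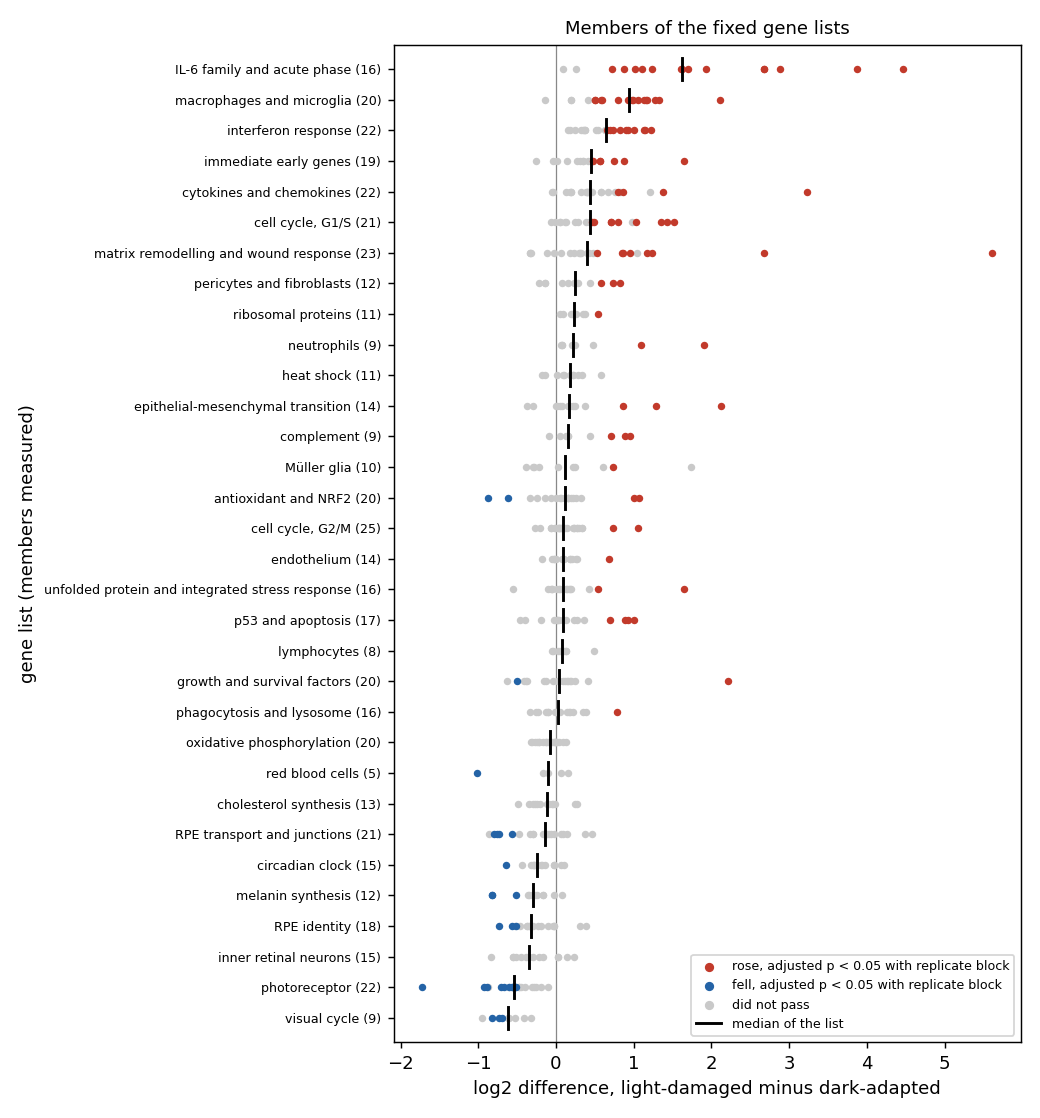
Log2 difference, light-damaged minus dark-adapted (horizontal axis), of each measured member of 32 gene lists (vertical axis, with the number measured), with red and blue points for members that rose or fell with the replicate block, grey points for the rest and black bars for medians. The IL-6 family and acute phase list has the highest median, 1.62, and the visual cycle list the lowest, -0.62.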

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

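Probe sets without exactly 1 gene symbol in the annotation used here numbered 10092 and took no part in the comparisons of genes. When all 45037 non-control probe sets were fitted together in limma, 3 of these 10092 were higher in light-damaged than in dark-adapted arrays without the replicate block. With the replicate block 93 were higher and 53 were lower. The largest rise among them was 2.91 ± 0.18 on the log2 scale, from 8.84 to 11.75, and the largest fall -1.27 ± 0.08, from 9.96 to 8.69 (n = 3 per group, errors with the block).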

How the results depend on the processing

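Array weights and the photoreceptor covariate moved the counts of genes most, followed by the replicate block and the settings that deal with the replicate 1 arrays, and the count of lists moved most with an estimated correlation. Settings named below as added were chosen after seeing the data. Against 9 genes called (9 higher, 0 lower, 9 at least 2-fold, 3 list members), quantile normalization gave 1 lower gene, cyclic loess 20 genes (18 higher, 2 lower, 20 at least 2-fold), a pseudocount of 16 gave 17 (16 higher, 1 lower, 17 at least 2-fold) and the mean of a gene's probe sets 28 (26 higher, 2 lower, 27 at least 2-fold). The ordinary unmoderated test called 0 genes, 0 higher and 0 at least 2-fold, with 1157 at an unadjusted p under 0.05, against 1080 in limma. Leaving out 1 array gave 3 to 12 genes, 3 to 12 higher, 0 lower, 3 to 12 at least 2-fold, 2 to 3 list members and 20 to 24 lists. The replicate block gave 908 genes (559 higher, 349 lower, 167 at least 2-fold, 114 list members). Array weights gave 5084 (2540, 2544, 286 and 264, in the same order), but their estimation stopped before convergence, with weights from 0.10 to 9.58 and the highest on both replicate 2 arrays. The photoreceptor covariate gave 3169 (2293, 876, 841 and 137), and 12 lists. Added settings gave, in the same order, 793 (576, 217, 184 and 115) without both replicate 1 arrays, 1082 (669, 413, 170 and 127) with a block of replicate 1 against 2 and 3, and 704 (490, 214, 153 and 101) with the Gapdh 3′ minus 5′ difference as a covariate. The replicate block gave 862 (524, 338, 171 and 109) with quantile normalization, 939 (516, 423, 163 and 120) with median centring, 1019 (613, 406, 173 and 120) with cyclic loess and 653 (365, 288, 117 and 84) with genes below the median level left out. On fewer residual degrees of freedom, it gave 1245 (827, 418, 191 and 141) without pair 1, 677 (392, 285, 194 and 98) without pair 2 and 228 (160, 68, 155 and 49) without pair 3. The 22 lists called by camera became 0 with an estimated correlation and 7 with fry. With the photoreceptor covariate 12 lists were called, 9 of them among the 22, and the others were Müller glia, heat shock and oxidative phosphorylation, while the photoreceptor list was not tested. Besides the RPE lists named above, it ended the calls of cytokines and chemokines, neutrophils, complement, pericytes and fibroblasts, epithelial-mesenchymal transition, inner retinal neurons, the unfolded protein response, G2/M and the circadian clock. Without both replicate 1 arrays 24 lists were called, with RPE transport and junctions lost and phagocytosis and lysosome, Müller glia and heat shock gained. With the photoreceptor covariate the median turned from 0.0947 to -0.0926 for G2/M genes, from -0.24 to 0.22 for circadian genes and from -0.08 to 0.21 for oxidative phosphorylation. It also turned from 0.21 to -0.07 for neutrophils, from 0.08 to -0.15 for lymphocytes and from 0.09 to -0.01 for endothelium. For growth factors it turned from 0.03 to -0.15, and for cholesterol synthesis from -0.11 to 0.15. Of these the G2/M, circadian and neutrophil lists lost their calls with the covariate (camera adjusted p = 0.6952, 0.5747 and 0.9105), while the oxidative phosphorylation list was called (adjusted p = 0.0192). The rest of these lists were called in neither fit. All 9 genes kept a difference above 0 in every setting that tested them. The cause of these differences was not tested. The photoreceptor covariate followed both the group and the replicate 1 arrays, so shifts with it do not tell these apart. With the block, the call of the unfolded protein response list by camera was lost and those of the other 21 lists were kept. Signal over background, for which no detection calls were used, limits the dimmest genes.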

Other observations

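Tests in this part that were chosen after the result was seen are those of retinal tissue, of dilution and of scaling, and the setting without both replicate 1 arrays was also chosen after the arrays were seen. Several list members passed in limma without both replicate 1 arrays but not with the replicate block. Crym, a thyroid hormone binding protein of Müller glia and neurons, differed by 2.36 without them (adjusted p = 2.7e-04) and by 1.73 in all arrays (adjusted p = 0.0520 with the block). Likewise the alarmin Il33 differed by 1.19 and the helicase subunit gene Mcm6 by 1.46, against 0.82 and 0.98 in all arrays. The transcription factor gene Sox2 differed by 0.90 against 0.60. These genes were picked after their values were seen.

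Xist, expressed from the inactive X chromosome, had a mean of 13.22 ± 0.19 (SD, n = 3) in dark-adapted and 13.18 ± 0.30 in light-damaged arrays. The Y-linked genes Uty, Kdm5d and Eif2s3y had means of 6.44, 5.73 and 4.44 in dark-adapted and 6.56, 5.80 and 4.33 in light-damaged arrays, and none of the 4 was called.

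The replicate 1 arrays of both groups stood apart. Less retinal tissue in them would raise RPE transcripts, but the visual cycle mean was lower there by a difference of -0.57, with an SD over its 9 genes of 0.44, and lay at -0.32 in dark-adapted and -0.82 in light-damaged arrays. RPE identity genes differed by only -0.02 and -0.17, and melanin synthesis genes by 0.21 and -0.04, so less retinal tissue was left open. A 3′ bias of the labelled RNA stays open as well. Both replicate 1 arrays lay above the other 4 in 2 of 4 further control differences, Gapdh 3′ minus middle and transferrin receptor. They did not for beta-actin 3′ minus middle or pyruvate carboxylase. The beta-actin 3′ minus 5′ difference, like that of Gapdh, was higher in the replicate 1 arrays, at 2.79 and 2.80 against 1.76 to 2.25 in the others. No biological explanation was tested, since the design gives none for a replicate number.

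Photoreceptor and visual cycle transcripts were lower in light-damaged arrays. Less retinal tissue in the light-damaged samples would lower cone and rod genes alike. The median of 4 cone genes was set against that of 3 genes of similar level taken as rod genes (Cngb1, Pde6a and Rp1). These 3 were the list members left after cone genes and some shared genes were removed, and were not checked for expression in rods alone. The cone median minus the rod median was -0.17, -0.26 and -0.51 in the 3 pairs, a mean of -0.31 ± 0.18 (SD, n = 3). The cone genes had been seen to fall furthest before this test. Nrl, a rod gene outside that range of levels, differed by -0.67. The gap thus depends on the rod genes taken, and less retinal tissue was left open. The visual cycle median averaged -0.58 ± 0.29 over the 3 pairs, but it shrank from -0.62 to -0.12 with the photoreceptor covariate. That covariate followed both the group and the replicate 1 difference, so the shrinkage cannot decide the cause of the fall, which was left open. Dilution of RPE RNA by that of other cells was left open as well, since the RPE identity median lay above that of the visual cycle by 0.29 ± 0.22 (SD, n = 3) but below it with the covariate, at -0.39 against -0.12. A loss of cone transcripts with light damage may be part of the fall, as a hypothesis.

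Macrophage and microglia transcripts were higher in light-damaged arrays. The median without the replicate 1 arrays was 0.89, with an SD over members of 0.51, which argues against those arrays as the cause. The lowest median over 3 other scalings was 0.91, but these moved the median of all genes by at most 0.02, so they tested little. A scaling of whole arrays would move all genes alike. The median difference was 0.93 for this list, -9.4e-05 for all genes and -0.54 for photoreceptor genes. These values argue against such a scaling as the cause of the rise relative to other genes. More cells of one unchanged kind would raise all members alike if only those cells expressed them and all probe sets responded alike. The SD over 15 members above the median level was 0.53, against a median standard error of 0.09, with Csf1r at -0.15 and Cd68 at 2.11. Neither condition was tested, so this explanation was left open. A change in the kind or state of myeloid cells with light damage may be part of the rise, as an untested hypothesis. Cell number and expression per cell were not measured apart.

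The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 9 genes, 9 at least 2-fold, and 3 list members, and the highest of the other splits gave 0 for each, so 1 split, the real one, reached each value. For camera with its preset correlation, 1 split reached 22 lists, the real one, and the highest other gave 16. Among the 4 splits that part all 3 pairs, fitted with the replicate block, the real one gave 908 genes and 21 lists, 1 split reaching each, and the highest others gave 0 and 18. The other 3 mix the light-damaged and dark-adapted arrays of 1 pair. Camera thus called lists in splits that mix the groups. Such splits keep part of the light difference, and some the replicate 1 difference, so they do not show what chance gives. Since camera called none with an estimated correlation, its calls with the preset correlation remain weak evidence here.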
